A study of Mus musculus with 6 samples.

How the data were processed

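Bulk RNA sequencing was measured in 6 libraries of lymphocytes sorted from mammary glands of pregnant mice at embryonic day 18.5, per the labels' protocols. The labels put 3 libraries in a CD8 beta+ T cell group and 3 in a group called double negative (DN) NK1.1+, whose cells they call lymphocytes in one place and T cells in another. They do not name the pair of markers that the DN cells lack. RNA was isolated with a micro-scale column kit and libraries were made with a Tecan kit for mouse RNA, per the labels' protocols. The single-cell, hashtag and receptor libraries that the labels mention were not used here.

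The values deposited by the authors were taken to be expected counts per gene, a unit that was inferred from the values and that the labels do not state. They hold at most 2 decimals, and their totals differ between libraries, so they were taken as not scaled between samples. The tool that made them is not named in the labels. The submitters' processing notes list the genome build mm10 and Cell Ranger 7.1.0, which is a tool for single-cell data. The aligner, the counting tool, the annotation, the use of strand and any removal of duplicate reads for the bulk libraries are not given in the sources used here. The 2 identifier headings of the table are swapped: the column headed as symbols holds Ensembl IDs, and the other one holds the symbols. All 55450 IDs and symbols matched GENCODE M21, an annotation of the same build, from which coordinates and gene types were taken. A total of 217 IDs share their symbol with another ID.

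The expected counts were rounded to whole numbers. Library totals were 7961360, 14367299 and 9568670 counts for the CD8 beta+ libraries and 11440721, 11905153 and 12820875 counts for the DN NK1.1+ libraries. A single count was worth between 0.0722 and 0.13 CPM, the usual unit of counts scaled to library size. Between 16552 and 18646 genes had a count in a library. CPM values use library sizes scaled by TMM factors, which lay between 0.9653 and 1.031. Pairs of libraries of one group differed by 9.23 to 25.4 chi-square units per degree of freedom over genes, so that none was a copy of another.

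The comparison was DN NK1.1+ against CD8 beta+, with 3 libraries each. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, model with the group alone, TMM). Genes passed a filter with a minimum count of 10 and a minimum total of 15, which left 13171. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these samples, which may be technical. Fold changes of genes with 3 or fewer counts over a group are given as the ratio of summed counts with its exact 95% binomial interval. Where a group had 0 counts, the ratio is a lower bound against 3 counts over the group. Such intervals and floors cover counting error only.

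The tests, alternatives and 26 gene lists were fixed before the data were examined. There were 18 biological lists and 8 lists of markers of other cell types. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes of 0.01), with Benjamini-Hochberg adjustment over the lists. Members were counted by direction after adjustment over all genes and after adjustment over the list alone. The rule for named genes was fixed then too. It took the sort genes Cd8a, Cd8b1, Cd4 and Klrb1c. It took the 5 genes with the largest change each way among called genes whose groups do not overlap, with a mean of at least 20 CPM in the higher group, leaving out predicted genes and receptor V, D and J segments. It took the 2 called members of each biological list with the largest change and at least 5 CPM, and the member of each marker list with the highest mean CPM. The rule named 49 genes, of which 1 is not reported here. Further list members are given as examples, and these and genes outside the lists were chosen after their values were seen.

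The fit was tested on simulated counts with the means and library sizes of these 13171 genes and dispersions from their trend over abundance. The spread of dispersions between genes of like abundance was not simulated. Of 81 genes changed by 1.5-fold, 17.3% were recovered, of 56 changed by 2-fold, 67.9%, and of 63 changed by 4-fold, 74.6%. Of the 105 calls, 5.7% were false. Of 200 simulated lists without change, camera called 4% at an unadjusted p under 0.05. It called 100% of 200 lists of 20 genes in which a part had been raised. Genes were simulated independently, so these shares do not cover lists whose members are correlated. Estimated correlations in the real lists ran from −0.0258 to 0.86.

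The alternatives tried were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, other filters on low counts, a replicate block, stricter thresholds, the removal of receptor segments, haemoglobin and milk protein genes, camera with an estimated correlation, the rotation test fry, and leaving out each library in turn. One more, without both libraries numbered 3, was chosen after seeing the data.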

Results

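Lymphocytes of the mouse mammary gland were profiled late in pregnancy. The study asked if unconventional lymphocytes within the mammary epithelium act on the differentiation of epithelial and basal cells. Of 6 bulk libraries, 3 came from CD8 beta+ T cells and 3 from DN NK1.1+ lymphocytes. NK1.1 is a surface receptor of natural killer (NK) cells and of some T cells. The depth was 7961360 to 14367299 counts per library. The comparison asked how DN NK1.1+ cells differed in expression from CD8 beta+ T cells of the same tissue. Values are mean CPM ± SD (n = 3 per group), and CD8 beta+ values are given before DN NK1.1+ values. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

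DN NK1.1+ libraries held almost no Cd8b1 transcripts, many more Klrb1c transcripts and a reduced but clear level of Cd8a. The groups are named by CD8 beta and NK1.1, the products of Cd8b1 and Klrb1c. Higher Cd8b1 in the one and higher Klrb1c in the other therefore follow from the sort, and their p-values test nothing beyond it. Cd8b1, which encodes the CD8 beta chain, fell from 949 ± 57.8 to 2.57 ± 1.58 CPM (log2 fold change −8.55, SE 0.326, adjusted p = 2.69e-06). Without DN NK1.1+ replicate 1 its log2 fold change was −9.14. Klrb1c, which encodes NK1.1, rose from 37.1 ± 5.68 to 639 ± 20.8 CPM (log2 fold change 4.10, SE 0.122, adjusted p = 7.94e-12). Cd8a, for the CD8 alpha chain, fell from 911 ± 85.8 to 162 ± 11.6 CPM (log2 fold change −2.49, SE 0.106, adjusted p = 4.40e-10). CD8 alpha may be among the unnamed markers that DN cells lack, so this fall and its p-value may follow from the sort too. The 3 DN NK1.1+ libraries had 174, 161 and 151 CPM of Cd8a. Cd4 was low in both groups, at 2.15 ± 2.54 and 1.36 ± 0.765 CPM, and did not pass the test (adjusted p = 0.714). Without CD8 beta+ replicate 3 its log2 fold change turned from −0.67 to 0.86. On build mm10 these protein-coding genes lie on chromosome 6: Cd8a from 71373427 to 71379173, Cd8b1 from 71322788 to 71337494, Klrb1c from 128778485 to 128789215 and Cd4 from 124864692 to 124888221.

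**Figure D1:**
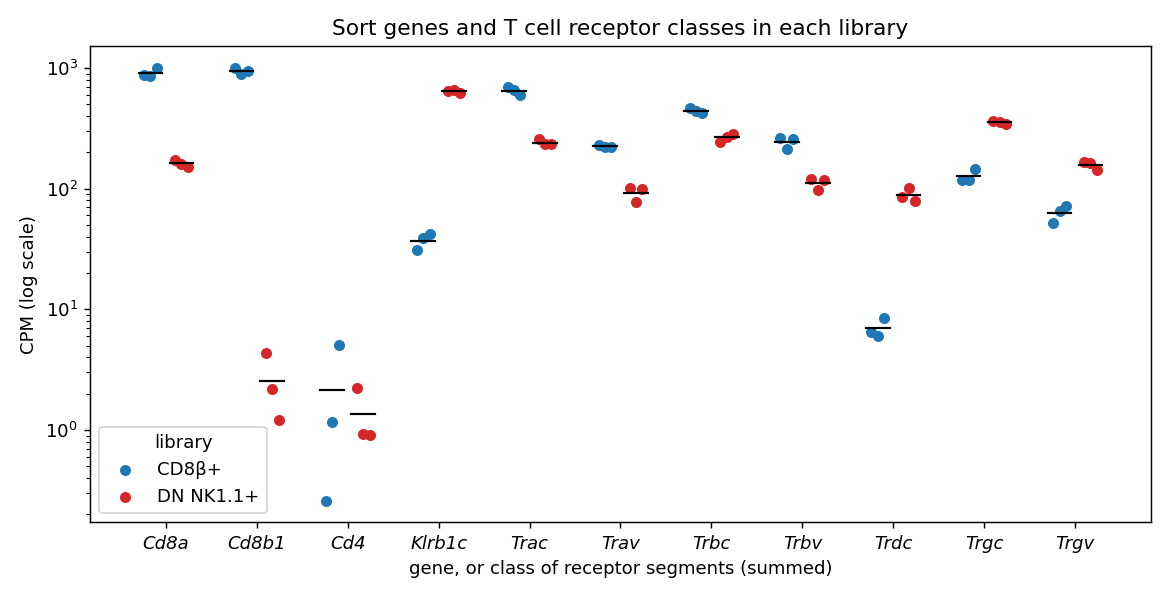
Each point is 1 library (CPM, log scale) and each black line the mean of the 3 libraries of a group, for the sort genes and for summed classes of T cell receptor segments. Cd8b1 fell from a mean of 949 to 2.57 CPM and Klrb1c rose from 37.1 to 639 CPM, while Cd8a stayed at 162 CPM in DN NK1.1+ libraries.

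Of 13171 genes tested, 1033 were higher and 789 lower in DN NK1.1+ libraries. Of these, 534 and 332 changed by at least 2-fold. Among genes with at least 20 CPM in the higher group, the 5 with the largest increase were genes or a pseudogene of NK receptors. Ncr1, which encodes the activating receptor NKp46, rose from 0.485 ± 0.182 to 273 ± 20.6 CPM (log2 fold change 9.21, SE 0.190, adjusted p = 1.85e-13). Its locus is on chromosome 7 from 4337724 to 4345164. Klra4, Klra8 and Klrb1b had log2 fold changes of 7.97, 7.64 and 7.52. That of Klra4 was 8.63 without CD8 beta+ replicate 3, and that of Klrb1b was 8.97 without CD8 beta+ replicate 2. The pseudogene Klra14-ps had 2 counts in CD8 beta+ and 789 in DN NK1.1+ libraries, a ratio of 336 with an exact 95% interval of 92.6 to 2780. Both low counts lay in CD8 beta+ replicate 2, and without that library Klra14-ps was at least 125-fold higher against 3 counts over the group. With the same minimum, the largest decreases below Cd8b1 were in Gzmk, Themis, Slamf1 and Fam169b. The granzyme gene Gzmk fell from 245 ± 33.4 to 4.23 ± 0.998 CPM (log2 fold change −5.85), and Themis, whose product acts in T cell receptor signalling, fell from 387 ± 4.49 to 9.23 ± 5.01 CPM (−5.40). Slamf1, for a surface receptor of lymphocytes, fell from 49.1 ± 12.2 to 1.51 ± 1.24 CPM (−4.99, and −5.83 without DN NK1.1+ replicate 3). Fam169b fell from 80.3 ± 20.9 to 2.72 ± 1.17 CPM (−4.89).

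The 3 values of one group lay apart from those of the other in 1028 of the higher and 783 of the lower genes. Over all tested genes this held for 30.6%, where chance gives 10%. Without CD8 beta+ replicate 1, 681 genes were higher and 499 lower. Genes of the Klra, Klrb1, Klrc and Gzm families, the Tcrg and Trav segments and the pair Trbc1 and Trbc2 resemble each other closely, so counts may have been split between them and values of single members are uncertain.

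Genes of the T cell receptor complex and other pan-T genes were lower as a group. Of 20 tested, 16 fell and 0 rose (0 and 16 adjusted over the list alone for higher and lower; camera adjusted p = 2.68e-16; adjusted p = 0.0533 with an estimated correlation). The decreases were unequal. Cd5 and Cd6, for inhibitory surface receptors of T cells, fell from 159 ± 11.1 to 10.1 ± 0.811 CPM and from 237 ± 15.3 to 16.8 ± 0.983 CPM. Bcl11b, for a transcription factor of T cell commitment, fell from 289 ± 14.9 to 53.3 ± 8.76 CPM. Trac, the constant gene of the receptor's alpha chain, fell from 649 ± 52.5 to 241 ± 12.9 CPM. Cd3e fell less, from 765 ± 19.4 to 522 ± 7.47 CPM. Cd3g, at 728 ± 63.8 and 665 ± 66.5 CPM (adjusted p = 0.501), and Zap70, at 109 ± 10.8 and 113 ± 9.69 CPM (adjusted p = 0.844), did not pass the test. Summed V segments of the alpha chain were at 225 ± 5.51 and 92.9 ± 12.9 CPM, and those of the beta chain at 245 ± 26.6 and 112 ± 11.9 CPM. The alpha chain sum includes segments that can also serve delta chains. Of these, Trav15d-1-dv6d-1 took 0.29% of the sum in CD8 beta+ and 6.58% in DN NK1.1+ libraries.

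Genes of the gamma-delta T cell receptor were higher in DN NK1.1+ libraries. Of 11 tested, 8 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 3.71e-09; adjusted p = 0.156 with an estimated correlation). Trdc, the constant gene of the delta chain, rose from 7.04 ± 1.32 to 88.3 ± 11.2 CPM (log2 fold change 3.65, SE 0.174, adjusted p = 1.35e-09). The variable segment Tcrg-V4 rose from 2.85 ± 0.956 to 25.0 ± 2.86 CPM (log2 fold change 3.11, SE 0.273, adjusted p = 1.27e-06). The constant genes Tcrg-C1 and Tcrg-C4 rose from 27.2 ± 1.05 to 115 ± 9.03 CPM and from 12.1 ± 4.31 to 74.3 ± 6.60 CPM. Class sums rose less: gamma constant genes from 128 ± 16.3 to 355 ± 10.9 CPM and gamma V segments from 62.7 ± 9.86 to 158 ± 12.7 CPM. Tcrg-C4 is also in the list of markers of NK cells and innate lymphoid cells. Which cells held these transcripts was not tested. The delta segment Trdv4 had 0 counts in CD8 beta+ and 65 in DN NK1.1+ libraries, at least 18.4-fold higher against 3 counts over the group. Summed V segments of the delta chain were low in both groups, at 2.56 ± 1.88 and 4.84 ± 0.281 CPM. CD8 beta+ replicate 3, at 4.736 CPM, lay within the range of the DN NK1.1+ libraries (4.525 to 5.072 CPM).

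NK receptors and adaptors were higher in DN NK1.1+ libraries. The list includes Klrb1c, whose rise follows from the sort. Members expressed in the same cells as Klrb1c may have been selected with it, so the list's p-value is not independent of the sort. Of 30 tested, 25 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 4.11e-28; adjusted p = 0.0985 with an estimated correlation). Klrk1, for the activating receptor NKG2D, rose from 107 ± 24.9 to 573 ± 35.0 CPM, and Klrc1, for the receptor chain NKG2A, rose from 115 ± 17.2 to 374 ± 18.6 CPM. The signalling adaptor genes Fcer1g and Tyrobp rose from 64.4 ± 13.9 to 818 ± 86.1 CPM and from 20.5 ± 6.57 to 343 ± 37.5 CPM. Hcst, Slamf7, Cd226, Cd160 and Klra10 did not pass the test. Markers of NK cells and innate lymphoid cells moved with this group: 12 of 15 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.98e-16). This call held with an estimated correlation (adjusted p = 0.0412), and the list shares Ncr1 and 5 other members with the NK receptors. Its member Khdc1a had 0 counts in CD8 beta+ and 289 in DN NK1.1+ libraries, at least 82-fold higher. Arg1 had 1 and 39 counts, a ratio of 33.2 with an exact 95% interval of 5.62 to 1340. Without CD8 beta+ replicate 3, which held the low count, Arg1 was at least 7.62-fold higher. Eomes, for a transcription factor of NK and memory T cells, was at 173 ± 2.39 and 190.0 ± 10.1 CPM (adjusted p = 0.392). At an unadjusted p under 0.05, and with DESeq2 or limma-voom, 0 pan-T genes were higher and 0 members of the gamma-delta and both NK lists were lower.

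**Figure D2:**
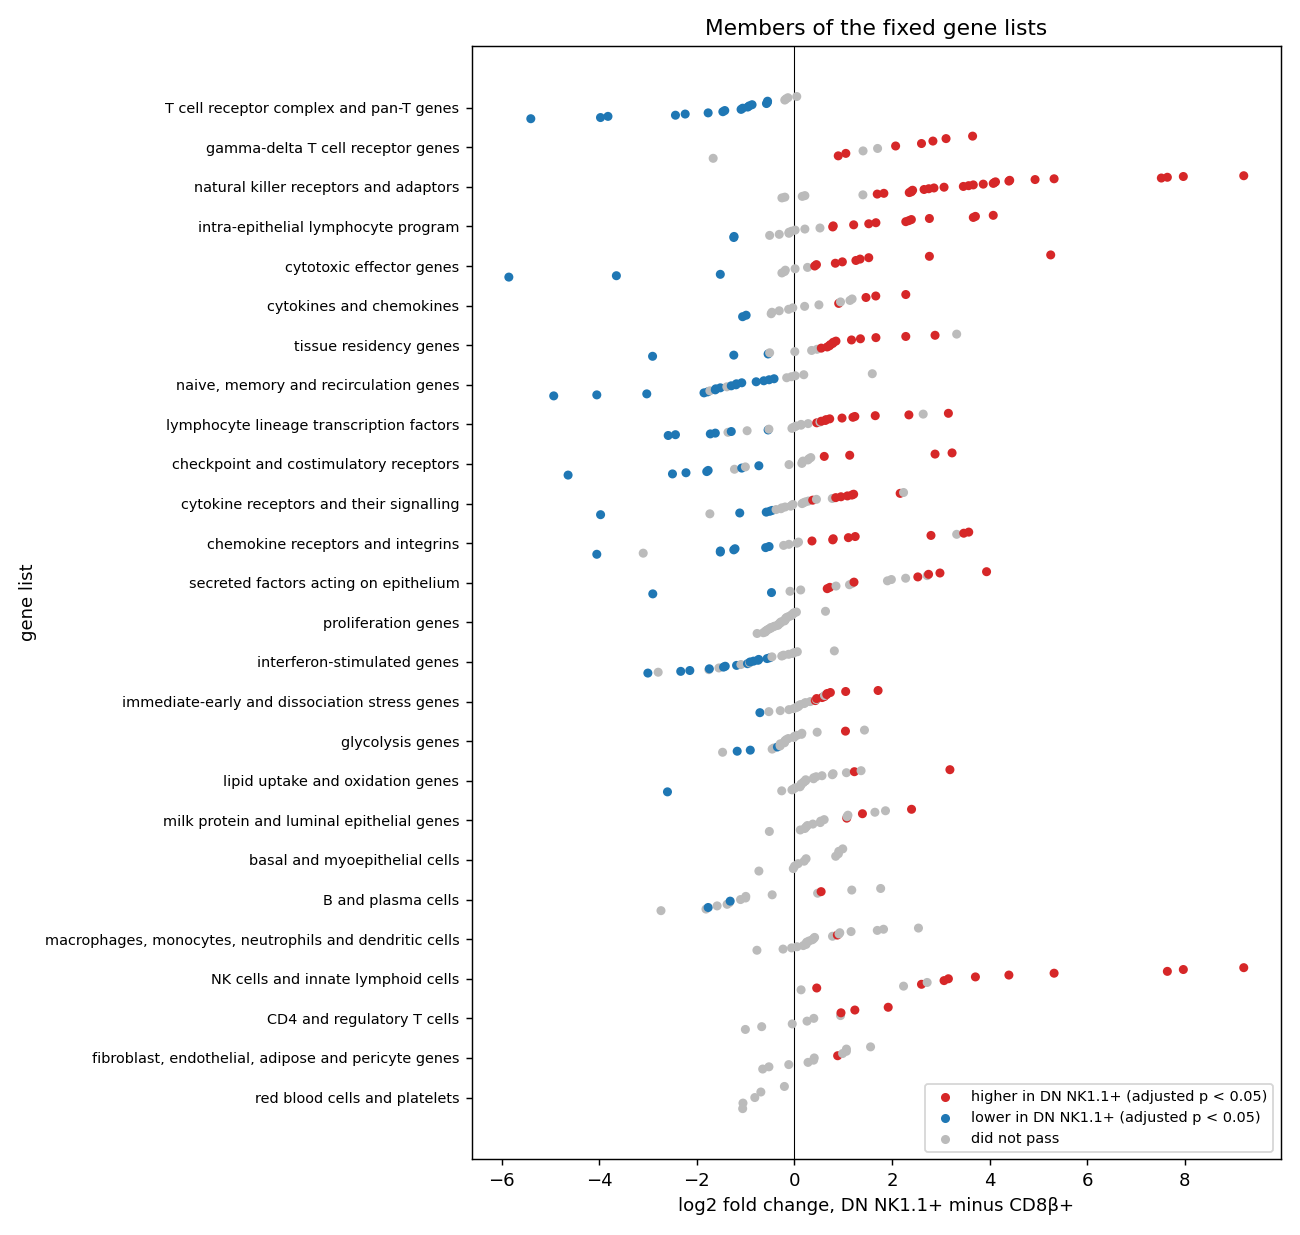
Each point is a tested member of a gene list, placed by its log2 fold change between DN NK1.1+ and CD8 beta+ libraries and coloured by whether it passed the edgeR test (Trdv4, Ccr9, Arg1 and Khdc1a, with 3 or fewer counts in a group, are not drawn). NK receptors lie to the right, with 25 of 30 higher, and pan-T genes to the left, with 16 of 20 lower.

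Of 23 genes of the intra-epithelial lymphocyte program, 12 rose and 3 fell (13 and 4 adjusted over the list alone; camera adjusted p = 3.96e-04; adjusted p = 0.385 with an estimated correlation). The list is not separate from others: it shares Fcer1g and Tyrobp, among others, with the NK receptors, and Gzma and Gzmb with the cytotoxic genes. Ikzf2, for the transcription factor Helios, rose from 41.8 ± 6.92 to 214 ± 27.6 CPM. Gzmb, for granzyme B, rose from 858 ± 77.3 to 2468 ± 117 CPM, and Itgae, for the integrin CD103, rose from 384 ± 48.8 to 662 ± 44.3 CPM. Ccr9, for a chemokine receptor of gut homing, was lower: it had 236 counts in CD8 beta+ and 2 in DN NK1.1+ libraries, a ratio of 139 with an exact 95% interval of 38 to 1150. Both low counts lay in DN NK1.1+ replicate 3, and without that library Ccr9 was at least 59.2-fold lower against 3 counts over the group. The tissue residency genes share 6 members with this list. Of 20 tested, 12 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 1.12e-04; adjusted p = 0.402 with an estimated correlation). Tnfrsf9, for the receptor 4-1BB, rose from 17.5 ± 3.37 to 129 ± 4.76 CPM, and Ahr, for the aryl hydrocarbon receptor, rose from 42.9 ± 8.35 to 137 ± 10.3 CPM. P2rx7, for a receptor of extracellular ATP, fell from 46.2 ± 17.6 to 6.11 ± 3.58 CPM, with a log2 fold change of −2.91, or −3.51 without DN NK1.1+ replicate 3. Cxcr6 fell from 203 ± 4.45 to 86.0 ± 3.89 CPM.

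Genes of naive, memory and recirculating T cells were lower. Of 23 tested, 16 fell and 0 rose (0 and 16 adjusted over the list alone for higher and lower; camera adjusted p = 4.76e-09; adjusted p = 0.178 with an estimated correlation). At an unadjusted p under 0.05, and with DESeq2 or limma-voom, 0 members were higher. The summed CPM of this list was 4818, 4804 and 3604 in CD8 beta+ replicates 1, 2 and 3, and 2384 to 2591 in DN NK1.1+ libraries. Dapl1 fell from 17.3 ± 9.70 to 0.566 ± 0.480 CPM, with a log2 fold change of −4.93, or −5.69 without DN NK1.1+ replicate 1. S1pr1, whose product directs exit from tissue, fell from 145 ± 17.0 to 40.1 ± 7.33 CPM, and Tcf7, for a transcription factor of naive and memory T cells, fell from 297 ± 70.9 to 121 ± 11.4 CPM. Ccr7, for a receptor of lymph node homing, was at 70.2 ± 38.3 and 4.24 ± 0.610 CPM (adjusted p = 0.0153), with 91.6, 93.0 and 25.9 CPM in the CD8 beta+ libraries. Its call ended without any one of the DN NK1.1+ libraries (adjusted p = 0.09 to 0.0915; 8.2e-12 to 0.0915 over all alternatives).

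Cytotoxic effector genes moved in both directions. Of 17 tested, 9 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0342; adjusted p = 0.532 with an estimated correlation). Gzma rose from 242 ± 33.8 to 1650.3 ± 133 CPM, and Prf1, for perforin, rose from 79.2 ± 9.81 to 201 ± 27.7 CPM. Gzmc rose from 0.892 ± 0.704 to 38.0 ± 7.84 CPM, with a log2 fold change of 5.25, or 5.90 without CD8 beta+ replicate 2. Gzmm fell from 16.3 ± 4.05 to 1.29 ± 0.555 CPM, as did Gzmk, and Nkg7 was at 846 ± 113 and 736 ± 113 CPM (adjusted p = 0.358). The list call ended without CD8 beta+ replicate 2 (adjusted p = 0.119) or DN NK1.1+ replicate 2 (0.0627; 0.022 to 0.532 over all alternatives). Of 16 cytokines and chemokines, 4 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.274). The chemokine genes Xcl1 and Ccl3 rose from 49.0 ± 7.87 to 239 ± 38.4 CPM and from 12.8 ± 3.45 to 40.7 ± 8.89 CPM. Tnf fell from 38.8 ± 4.39 to 18.6 ± 3.84 CPM, and Ifng was at 76.7 ± 15.5 and 55.2 ± 10.3 CPM (adjusted p = 0.0710).

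Of 18 tested genes in the list named secreted factors acting on epithelium, 7 rose and 2 fell (9 and 2 adjusted over the list alone). The camera adjusted p was 3.17e-05, or 0.193 with an estimated correlation. Not every member need be secreted or act on epithelium, and neither was tested. Vegfa, for a vascular growth factor, rose from 3.24 ± 0.616 to 26.04 ± 6.71 CPM (log2 fold change 2.98, SE 0.271, adjusted p = 1.82e-06). Tgfa, for a ligand of the EGF receptor, rose from 0.374 ± 0.150 to 5.74 ± 2.52 CPM (log2 fold change 3.94, SE 0.622, adjusted p = 4.17e-04). Bmp7 and Tgfb3 rose from 5.16 ± 0.842 to 29.9 ± 7.64 CPM and from 1.999 ± 0.801 to 13.2 ± 0.654 CPM. Tgfb1 rose from 138 ± 9.44 to 229 ± 10.6 CPM. Tnfsf11, for the cytokine RANKL, fell from 3.17 ± 0.168 to 0.418 ± 0.310 CPM, and Areg, for another EGF receptor ligand, was at 0.361 ± 0.421 and 2.35 ± 0.398 CPM (adjusted p = 0.0900). The summed CPM of this list was 232, 257 and 281 in CD8 beta+ and 423, 467 and 478 in DN NK1.1+ libraries. In the same libraries, milk protein and luminal epithelial genes summed to 1124, 807 and 1040 CPM and to 570, 1326 and 2471 CPM. Genes of macrophages, monocytes, neutrophils and dendritic cells summed to 554, 634 and 675 CPM and to 1015, 559 and 843 CPM. Epcam, a member of the luminal list, rose from 6.05 ± 1.79 to 32.0 ± 1.04 CPM. Its small spread in DN NK1.1+ libraries did not follow their luminal sums of 570 to 2471 CPM.

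Transcription factors and receptors held opposed changes. Of 29 lineage transcription factors, 11 rose and 6 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.329). Irf8 and Nfil3 rose from 16.3 ± 2.42 to 145 ± 8.69 CPM and from 32.0 ± 3.84 to 101 ± 5.53 CPM. Irf4 and Rora fell from 88.6 ± 12.4 to 14.8 ± 2.59 CPM and from 133 ± 10.2 to 40.4 ± 3.43 CPM. Zbtb16, for the factor PLZF of innate-like T cells, was at 1.34 ± 1.13 and 8.02 ± 5.91 CPM (adjusted p = 0.201). Of 20 checkpoint and costimulatory receptors, 4 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.405, direction down). The mean log2 fold change of this list was −0.39 and its median 0.02, or −0.00407 with upper quartile scaling. Pdcd1, for PD-1, fell from 27.5 ± 7.95 to 1.07 ± 1.11 CPM, with a log2 fold change of −4.64, or −5.98 without DN NK1.1+ replicate 3. Icos fell from 118 ± 11.1 to 25.2 ± 6.54 CPM, and Cd200r1 rose from 3.43 ± 1.12 to 33.1 ± 6.53 CPM.

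Of 27 cytokine receptors and signalling genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.561). Il2rb, for a receptor chain of IL-2 and IL-15, rose from 985 ± 92.0 to 2287 ± 276 CPM, and Il12rb2 rose from 67.5 ± 12.3 to 304 ± 27.7 CPM. Il6ra fell from 43.0 ± 19.2 to 2.73 ± 0.850 CPM. Of 22 chemokine receptors and integrins, 8 rose and 8 fell (9 and 10 adjusted over the list alone; camera adjusted p = 0.885, direction down). The rotation test fry placed this list higher (adjusted p = 0.594; 0.387 to 0.97 over all alternatives), and its median log2 fold change turned from −0.03 to 0.02 with scaling by library size only. The integrin genes Itgam and Itga2 rose from 9.09 ± 1.25 to 108 ± 11.9 CPM and from 20.6 ± 8.80 to 145 ± 9.92 CPM. Itga4 and Cxcr3 fell from 1737 ± 258 to 747 ± 5.88 CPM and from 136 ± 5.92 to 47.4 ± 10.6 CPM.

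Interferon-stimulated genes were lower in DN NK1.1+ libraries. Of 27 tested, 14 fell and 0 rose (0 and 18 adjusted over the list alone for higher and lower; camera adjusted p = 2.18e-09; adjusted p = 0.0985 with an estimated correlation). At an unadjusted p under 0.05, and with DESeq2 or limma-voom, 0 members were higher. Ifi27l2a fell from 26.3 ± 6.28 to 3.25 ± 1.31 CPM and Oas3 fell from 86.4 ± 11.99 to 17.2 ± 3.01 CPM. Isg15 was at 2.58 ± 0.298 and 4.54 ± 1.42 CPM (adjusted p = 0.297). Of 23 immediate-early and dissociation stress genes, 9 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.402 with an estimated correlation). Fos and Atf3 rose from 101 ± 25.7 to 210.4 ± 18.9 CPM and from 5.54 ± 2.57 to 18.4 ± 4.22 CPM. Hsph1 fell from 256 ± 31.9 to 157 ± 37.9 CPM, and Hspa1a was at 92.8 ± 21.5 and 98.5 ± 25.7 CPM (adjusted p = 0.886).

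Of 22 glycolysis genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0425; adjusted p = 0.55 with an estimated correlation). Slc16a1, for a lactate transporter, fell from 124 ± 6.85 to 55.1 ± 7.23 CPM, and Tpi1, for a glycolytic enzyme, rose from 38.4 ± 5.31 to 79.5 ± 8.11 CPM. The list call ended without CD8 beta+ replicate 1 or 3 (adjusted p = 0.166 and 0.0764), without DN NK1.1+ replicate 1 or 2 (0.152 and 0.0548) and with fry (0.0763; 0.0237 to 0.55 over all alternatives). Of 23 genes of lipid uptake and oxidation, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0138; adjusted p = 0.385 with an estimated correlation). The call ended without CD8 beta+ replicate 1 (adjusted p = 0.0593; 0.00325 to 0.385 over all alternatives). Camera placed the list higher, and the member Apobec2 moved the other way. Apobec2 fell from 6.23 ± 3.53 to 1.01 ± 0.664 CPM (edgeR adjusted p = 0.0108). Its call ended without CD8 beta+ replicate 3 (0.0812, and 5.27e-04 to 0.0812 over all alternatives).

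Of 31 proliferation genes, 0 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 1 was higher and 4 lower. DESeq2 called 1 higher and 2 lower, and limma-voom called 1 higher and 0 lower. Camera placed the list lower (camera adjusted p = 0.0167; adjusted p = 0.641 with an estimated correlation). Its summed CPM was 3974 in CD8 beta+ replicate 3 and 2577 to 2777 in the other 5 libraries. The list call ended without CD8 beta+ replicate 3 (adjusted p = 0.547), without DN NK1.1+ replicate 1 or 2 (0.0881 and 0.0538), without both libraries numbered 3 (0.137) and with fry (0.455; 3.76e-04 to 0.641 over all alternatives).

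Markers of other cell types were present and differed within groups. Milk protein and luminal epithelial genes summed to 1124, 807 and 1040 CPM in CD8 beta+ and to 570, 1326 and 2471 CPM in DN NK1.1+ libraries. Of 16 tested, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0342; adjusted p = 0.641 with an estimated correlation). At an unadjusted p under 0.05, and with DESeq2 or limma-voom, 4 were higher and 0 lower. The call ended without CD8 beta+ replicate 2 (adjusted p = 0.153), without DN NK1.1+ replicate 2 or 3 (0.0538 and 0.405), without both libraries numbered 3 (0.304) and with fry (0.308; 1.07e-05 to 0.641 over all alternatives). Epcam, for an epithelial adhesion molecule, rose from 6.05 ± 1.79 to 32.0 ± 1.04 CPM. The casein gene Csn2 was at 372 ± 78.3 and 483 ± 395 CPM (adjusted p = 0.832), and its log2 fold change turned from 0.38 to −0.47 without DN NK1.1+ replicate 3.

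Basal and myoepithelial genes were highest in the library numbered 3 of each group. They summed to 24.2, 18.2 and 176 CPM in CD8 beta+ and to 15.7, 26.7 and 242 CPM in DN NK1.1+ libraries. Of 10 tested, 0 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone; camera adjusted p = 0.94), and 0 passed at an unadjusted p under 0.05, with DESeq2 or with limma-voom. Acta2, for smooth muscle actin, was at 75.9 and 94.1 CPM in the libraries numbered 3 and at 5.95 to 11.2 CPM in the other 4. Its log2 fold change was 0.20, or −0.20, −0.27 and −2.13 without CD8 beta+ replicate 1, CD8 beta+ replicate 2 and DN NK1.1+ replicate 3. Fibroblast, endothelial, adipose and pericyte genes summed to 74.4, 50.6 and 226 CPM and to 152, 52.8 and 260 CPM. Of 11 tested, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.541), with the same counts at an unadjusted p under 0.05, with DESeq2 and with limma-voom. The list passed as higher without DN NK1.1+ replicate 2 (adjusted p = 0.0384; 0.0384 to 0.88 over all alternatives). Pecam1, for an adhesion molecule of endothelial and blood cells, rose from 31.8 ± 8.05 to 58.9 ± 9.51 CPM. Without both libraries numbered 3, an alternative chosen after seeing the data, 1207 genes were higher and 1024 lower.

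**Figure D3:**
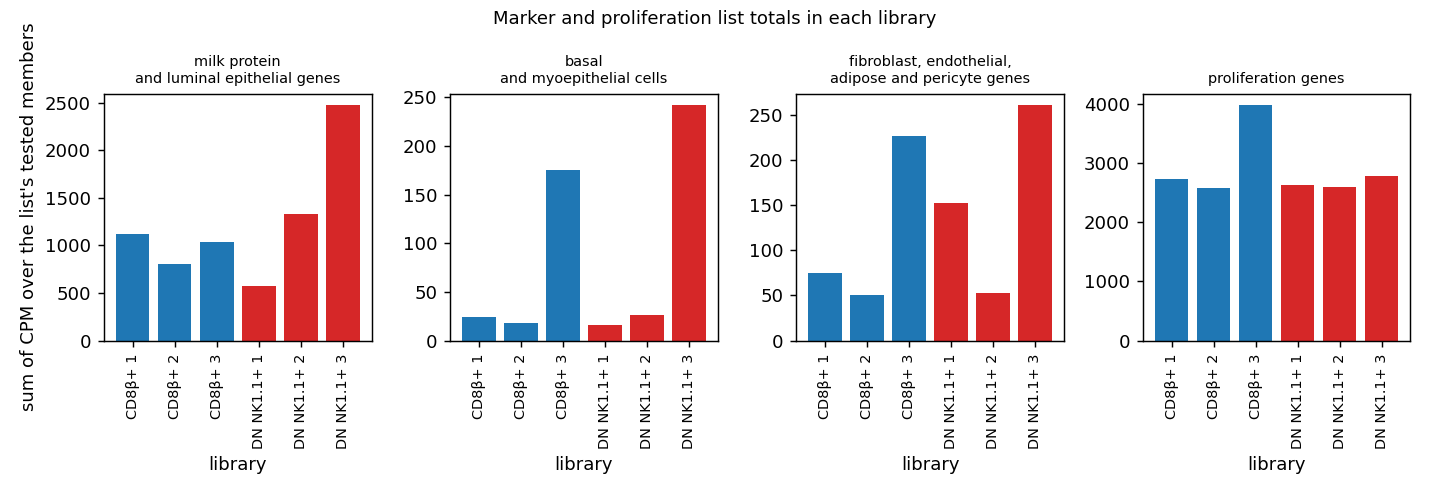
Bars give the summed CPM of the tested members of 4 gene lists in each library, from 0. Basal and myoepithelial genes reached 176 and 242 CPM in the library numbered 3 of each group and 15.7 to 26.7 CPM in the other 4.

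Of 15 B and plasma cell genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.14). The heavy chain gene Ighm rose from 186 ± 31.4 to 271 ± 21.7 CPM (adjusted p = 0.00603), and Cd79b, of the B cell receptor, fell from 10.9 ± 3.07 to 4.35 ± 1.42 CPM. The list passed as lower without CD8 beta+ replicate 3 (adjusted p = 0.0382) or DN NK1.1+ replicate 1 (0.0376; 0.00515 to 0.661 over all alternatives). Of 20 macrophage, monocyte, neutrophil and dendritic cell genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0167; adjusted p = 0.585 with an estimated correlation). Of its members, 4 were higher and 0 lower at an unadjusted p under 0.05; DESeq2 called 2 higher and limma-voom 1, with 0 lower in each. The call ended without CD8 beta+ replicate 1 or 2 (adjusted p = 0.166 and 0.0645), without DN NK1.1+ replicate 1 (0.11) and with fry (0.225; 4.7e-05 to 0.585 over all alternatives). Csf1r, for a receptor of macrophages, rose from 15.3 ± 3.78 to 28.3 ± 9.20 CPM. Cd74, for the class II invariant chain, was at 258 ± 15.6 and 319 ± 79.2 CPM (adjusted p = 0.298) and passed without DN NK1.1+ replicate 2 (0.0116; 0.0116 to 0.756 over all alternatives).

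Of 9 CD4 and regulatory T cell genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0692). Of these, 4 were higher at an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 2, with 0 lower in each. The list passed as higher without CD8 beta+ replicate 3 (adjusted p = 0.0115) or DN NK1.1+ replicate 2 (0.042; 0.00609 to 0.532 over all alternatives). Capg, for an actin-capping protein that other cells also make, rose from 16.7 ± 4.87 to 63.2 ± 4.70 CPM. Of 5 red blood cell and platelet genes, 0 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone; camera adjusted p = 0.102), and 0 passed at an unadjusted p under 0.05, with DESeq2 or with limma-voom. The list passed as lower without CD8 beta+ replicate 3 (adjusted p = 0.00897; 0.00878 to 0.586 over all alternatives). Alas2, for an enzyme of haem synthesis, was at 11.9 ± 4.84 and 7.39 ± 2.68 CPM (adjusted p = 0.2803). Mitochondrial genes took 9.48 ± 1.15% of counts in CD8 beta+ and 8.21 ± 0.811% in DN NK1.1+ libraries. Ribosomal protein genes took 8.37 ± 0.876% and 6.75 ± 0.0389%.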

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

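The alternative without both libraries numbered 3 was chosen after seeing the data. Other scalings, DESeq2, limma-voom, both other filters, the removal of receptor, haemoglobin and milk genes, and that alternative gave 973 to 1207 higher and 668 to 1027 lower genes, against 1033 and 789. In these, with a replicate block and without any 1 library, no gene was called in the opposite direction. Leaving out 1 library gave 681 to 1093 higher and 499 to 883 lower genes; fewer samples enter such fits. Stricter by construction, a 2-fold minimum left 534 and 332 genes and an adjusted p under 0.01 left 629 and 453.

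Camera called 11 lists higher and 5 lower. With an estimated correlation 1 was higher, the markers of NK and innate lymphoid cells, and 0 lower. Fry called 11 higher and 3 lower: the proliferation (adjusted p = 0.455), glycolysis (0.0763), milk and luminal (0.308) and macrophage (0.225) lists lost their call, and cytokines (0.0261) and cytokine receptors (0.017) gained one. Without both libraries numbered 3, the proliferation (0.137) and milk and luminal (0.304) lists lost their call, and the B cell (0.0284), CD4 (0.00609) and red blood cell (0.0187) lists gained one. Leaving out 1 library gave 8 to 12 higher and 3 to 5 lower. The cause was not tested.

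A pairing of the samples by replicate number was not established, since the labels state none and not every pair correlated by over 0.1. Libraries numbered 1, 2 and 3 correlated by −0.05, 0.19 and 0.26 in their deviations from the group means. The last 2 values were the highest of all pairs, while CD8 beta+ replicate 1 and DN NK1.1+ replicate 1 correlated best with another number. With a replicate block, 1137 genes were higher and 945 lower, and 10 lists higher and 6 lower. The cytotoxic (adjusted p = 0.0747) and glycolysis (0.0659) lists lost their call, and the B cell (0.00515) and red blood cell (0.00878) lists gained one.

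Of 49 named genes, 42 kept direction and call under the alternatives run on them: RLE, DESeq2, limma-voom, a replicate block, each library left out, and both libraries numbered 3 left out. Cd4, Csn2 and Acta2, which had no call, changed sign. Without 1 library their log2 fold changes were −1.23 to 0.86, −0.47 to 0.82 and −2.13 to 1.92. Without both libraries numbered 3 they were 1.08, −0.45 and −0.40, and with a replicate block Acta2 was at −0.10. The cause was not tested. Without CD8 beta+ replicate 1 Acta2 was at −0.20, and without CD8 beta+ replicate 2 at −0.27. Depth limits genes near 0, since 1 count was worth 0.0722 to 0.13 CPM. Of simulated genes changed by 1.5-fold, 17.3% were recovered; what sets that share was not tested.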

Other observations

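The genes and tests of this part were chosen after the results were seen, except the count over other splits of the libraries. Some genes of signalling below T cell and NK receptors rose and others fell (edgeR adjusted p from 6.14e-10 to 3.12e-05 for the 11 called ones named next); they were not tested as a group. The kinase genes Syk and Lyn rose from 14.6 ± 3.12 to 96.6 ± 1.16 CPM and from 23.1 ± 2.73 to 166 ± 15.6 CPM between CD8 beta+ and DN NK1.1+ libraries (n = 3 each). Plcg2, for a phospholipase of NK and B cell signalling, rose from 17.9 ± 3.81 to 162 ± 9.68 CPM. The adaptor genes Lat2 and Clnk rose from 5.04 ± 0.795 to 54.1 ± 2.96 CPM and from 8.13 ± 1.78 to 67.9 ± 6.79 CPM. The kinase genes Txk and Tec rose from 114 ± 19.9 to 248 ± 17.9 CPM and from 31.4 ± 5.83 to 75.6 ± 7.83 CPM, and Vav3 rose from 34.6 ± 6.16 to 91.6 ± 14.3 CPM. Lat fell from 169.9 ± 7.03 to 36.0 ± 2.39 CPM, Plcg1 fell from 219 ± 8.81 to 61.5 ± 2.82 CPM and Grap2 fell from 299.6 ± 10.9 to 92.9 ± 10.2 CPM. The T cell kinase gene Zap70 was at 109 ± 10.8 and 113 ± 9.69 CPM (adjusted p = 0.844). Lat is also among the pan-T genes. Of other called genes, Spry2, for an inhibitor of receptor tyrosine kinase signalling, was 19.4-fold higher (adjusted p = 4.01e-11) and Cd7 3.94-fold higher (3.97e-08). Ly6a was 16.6-fold lower (adjusted p = 2.00e-04) and Plac8 8.82-fold lower (4.57e-10).

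Among alpha chain V segments, Trav15d-1-dv6d-1, which can also serve delta chains, took 0.29 ± 0.192% of segment counts in CD8 beta+ and 6.58 ± 0.63% in DN NK1.1+ libraries. Trav11d, of the family used by invariant NKT cells, took 0.65 ± 0.29% in CD8 beta+ and 0.35 ± 0.378% in DN NK1.1+ libraries. Among gamma chain V segments, Trgv2 took the most in both groups, 87.2 ± 4.12% in CD8 beta+ and 71.9 ± 2.45% in DN NK1.1+ libraries, and Tcrg-V4 took 4.46 ± 0.869% in CD8 beta+ and 15.8 ± 0.592% in DN NK1.1+ libraries. These shares were not tested, and counts may be split between similar segments.

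The real split of the 6 libraries gave 1822 genes past the threshold, and the highest of the other 9 splits gave 4. Of the 10 splits, only 1, the real one, gave as many, and 10 splits cannot give a share under 0.05. Every other split mixes both groups on each side, so the group difference adds to the spread within sides and lowers its count. Those counts therefore do not measure what chance alone would give.

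Cd8a stayed at 17.8% of its CD8 beta+ level in DN NK1.1+ libraries and Cd8b1 at 0.271%. CD8 beta+ cells carried over in the sort would bring both transcripts in their usual ratio. The log2 fold changes differed by 6.06 (SE 0.343), which argues against such cells as the main source of Cd8a. Cd8a transcripts of DN NK1.1+ cells, or of other cells without Cd8b1, may account for it; this was not tested.

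Pan-T genes were lower and NK receptor genes higher in DN NK1.1+ libraries. If these held only cells without a T cell receptor, beta chain V segments would be near absent. Yet these segments stayed at 45.6% of their CD8 beta+ level (SD 4.86, from the spread of the DN NK1.1+ libraries alone). Cd8b1 stayed at only 0.271%, so dilution was considered for T cells otherwise like those of the CD8 beta+ libraries. It would lower pan-T genes by no more than the factor of the V segments. Beyond 2 standard errors of each gene, 8 of 20 lay below that factor, Themis, Cd5 and Cd6 the farthest. The factor was taken as exact, so its own error was left out. Of the 8, Trac and Ubash3a, with log2 fold changes of −1.43 and −1.47, lay nearest to the factor's log2 value of −1.13. The 9 above it do not test dilution, since the added cells may express those genes too. T cells that carry NK receptors, with or without NK cells beside them, could give these values, such as alpha chain V segments at 41.3%. That share includes segments that can also serve delta chains. Sums over cells cannot separate a mixture from 1 kind of cell.

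In both groups the library numbered 3 was highest for 10 of 10 tested basal genes and for 7 of 11 fibroblast, endothelial, adipose and pericyte genes. A candidate explanation is cells or RNA of basal and stromal tissue in those 2 preparations, which a T cell sort should remove. Of 29 other tested genes of these tissues, outside the lists that showed the pattern, 25 (86.2%) were highest in the library numbered 3 of both groups, against 15.4% of all tested genes and 11.1% by chance. The most counted of them, Gsn, was at 35.6 and 71.9 CPM there and at 15.4 to 28 CPM in the other 4 libraries, so that lymphocytes may express some of these genes. The labels give no batch and no biological explanation was tested; 21 of 31 proliferation genes were also highest in those 2 libraries.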
